A study of Mus musculus with 41 samples.

How the data were processed

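Processed files of 22 libraries of the mouse cell line C2C12 were used: 12 RNA-seq libraries (3 each of control and mH2A1.2-knockdown myoblasts, MB, and myotubes, MT), 4 ATAC-seq, 4 mH2A1.2 ChIP-seq and 2 Pbx1 ChIP-seq libraries. Groups came from the sample titles and replicate numbers from the same titles. Other groups that the labels name, among them histone H3K27 marks, ChIP in knockdown cells and the IgG and input libraries, were not analysed here. Peaks were not related to genes, because no gene coordinates of the mm9 build were used here.

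The RNA values were deposited as RPKM, reads per kilobase of transcript scaled to library size, in 1 table of 22552 gene symbols, each listed once, and per the submitters' processing notes Bowtie, TopHat and Cuffdiff were among the tools used, with no role or version given. RPKM is scaled by library size, so reads are not known; the scaling factors, the annotation and the treatment of reads from near-identical genes are not given in the sources used here. An exact 0 can be a failed estimate: 4344 genes stood at 0 in all 12 libraries, and Eef1a1 and Ubc, which every cell uses, at 0 in all MB libraries. Gapdh was at 0.169 to 0.955 RPKM, far below what an abundant transcript gives, and whether both stages were quantified in 1 run is not given in the sources used here. Such genes affect the comparisons between stages; in 1 alternative the 200 tested genes that stood at 0 throughout a group or were small RNA genes were left out.

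Peaks were called per library by the authors with MACS2 2.0.10.20131216 at a q threshold of 0.05 for ATAC and mH2A1.2, per the file headers, on mm9 per the submitters' processing notes. These deposited lists give each peak's pileup (a signal, the height in tags), its fold enrichment (a ratio) and its -log10 p and -log10 q. The Pbx1 lists were deposited in narrowPeak form with a score, 10 times the -log10 q rounded down, fold and -log10 p and q columns, and without a header, so their depth and caller settings are not known. Per the file headers the mH2A1.2 peaks were called against IgG in MB and against input in MT, replicate 2 in MT used combined files, and ATAC peaks were called without a control. Whether ATAC reads were shifted for the transposase is not given in the sources used here. Per the labels, mH2A1.2 replicate 1 used an antibody to mH2A1.2 and replicate 2 one to mH2A1 from another maker.

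Genes with an RPKM of at least 1 in at least 3 of the 12 libraries were tested (11710). Values were taken as log2(RPKM + 1), and fold changes are on that scale, which understates the change of low genes. limma 3.58.1 in R 4.3.3 fitted 1 mean per group (lmFit, eBayes with a mean-variance trend), with 7 residual and 2.8 prior degrees of freedom, and tests were two-sided. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05. The comparisons were control differentiation, the knockdown in MB and in MT, differentiation in knockdown cells, and the interaction (the knockdown effect in MT minus that in MB). Control MT replicates 1 and 2 differed by less than other replicate pairs: 101 tested genes (0.863%) lay over 2-fold apart, against 317 to 1094 in the other 11 pairs. They entered as their mean, which left 11 samples; this departs from the design fixed at first, whose 12 separate libraries are given as an alternative. Median standard errors were 0.207 for control differentiation and for the knockdown in MT, 0.185 for the other single contrasts and 0.277 for the interaction.

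The numbers in the titles pair the MB samples: deviations from the group means correlated between same-numbered control and knockdown libraries at r = 0.35, 0.31 and 0.37. In MT they were 0.08, 0.18 and 0.18, and between stages -0.06, 0.11 and 0.13 in control and 0.24, -0.04 and 0.24 in knockdown cells. The lowest value of each comparison was small or negative, so pairing by number was not shown for those samples, nor excluded. Control MT replicates 1 and 2 were nearly the same, so the check cannot tell their numbers apart. Some list levels set replicate 3 apart in every group, as for neural markers (4.33 against 5.79 and 5.71 in knockdown MT), and those of other lists did not. The labels do not say what a number marks. The fits without a block stayed the reported ones.

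The groups, comparisons, tests, naming rule, 29 gene lists and most alternatives were chosen before the data were examined. Of 777 list members, 642 were tested, and 28 lists had at least 5 tested members. The lists were myogenic regulators, sarcomere, excitation-contraction coupling and neuromuscular junction, fusion and adhesion, DNA replication, mitosis, cell cycle inhibitors and exit, p53 targets, respiratory chain, glycolysis and creatine metabolism, interferon response, inflammatory and secreted factors, extracellular matrix, smooth muscle and stress fibre genes, TALE and Hox genes, histone variants and chaperones, H3K27 writers and erasers, ADP-ribose and NAD metabolism, imprinted genes, Notch and TGF-beta family, insulin-like growth factor signalling, unfolded protein response, cholesterol synthesis, muscle splicing regulators and ribosomal proteins, and the markers of adipocytes, bone and cartilage, neural cells, and blood and endothelium. Lists were tested with camera, which compares a list with the other genes, at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move, on balance, one way. With the estimated correlation no list passed in any comparison. The named genes were the target gene; the 6 rising and 6 falling genes with the largest log2 change past the threshold, at a mean of at least 10 RPKM in the higher group and without overlap between the libraries of the groups (the interaction had no overlap rule); and up to 4 members per list past the threshold, the 2 largest rises and 2 largest falls, or else the 2 members with the highest mean as values. Predicted, clone, microRNA and small nucleolar RNA symbols were passed over, except Gm7325, which a fixed list names. Genes listed at 0 throughout a compared group were passed over too, a change to the naming rule made after the data were seen; it left out Eef1a1, Ubc and Filip1l among the largest changes between stages. For regions it was the 3 peaks of replicate 1 with the highest score in each stage-only set.

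For the overlap of contrasts that share libraries, 100 simulations of unchanged groups gave the values chance would give. Peak sets were compared in Python 3.11.15 with numpy 2.4.6. A peak was shared where it overlapped by at least 1 bp, a stage-only peak lay in both replicates of a stage and in neither of the other, and shares were tested against 1000 seeded circular shifts along each chromosome (100 in the alternatives), two-sided; chromosome ends were the highest coordinate in any peak list. Figures were drawn with matplotlib 3.10.9.

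The fit was tested in 5 simulations of 11710 genes, 200 changed in each. These had a mean above 3 on the log2 scale, so the shares recovered do not cover low genes. Of log2 changes of size 1, 73.6% were recovered for the knockdown in MB and 63.2% for that in MT, and of size 3, 98.8% and 98.4%, with 43 false calls over the 5 simulations of either comparison. With camera a shifted list was called in 5 of 5 simulations, and 0 other lists were. Genes were not simulated as correlated (estimate for the mitosis list 0.708), so false calls of such lists were not tested.

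Alternatives were a pseudocount of 0.1, no filter, a mean RPKM of at least 5, quantile and median scaling, no mean-variance trend, only the 2 groups compared, the replicate block (fitted over the 12 separate libraries, since the merged pair carries no single number), and leaving out each library. For peaks they were a -log10 q of at least 10, equal numbers of top peaks, an overlap of at least 50% of the shorter peak, autosomes alone, shifts of 1 Mb, and leaving out each replicate. Chosen after the data were seen were the 12 libraries as separate samples, leaving out genes listed at 0, the block over the 6 MB libraries, and leaving out the 2 libraries that stood apart.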

Results

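C2C12 cells, an immortalised line of mouse myoblasts that stop dividing and fuse into multinucleated myotubes when serum is withdrawn, were profiled as growing myoblasts (MB) and as myotubes (MT). The series addresses how macroH2A1.2 (mH2A1.2) takes part in muscle differentiation, in the opening of chromatin and in the binding of the homeodomain factor Pbx1. MacroH2A1.2 is a splice form of macroH2A1, a histone H2A variant with a large domain outside the histone fold, encoded by H2afy. Polyadenylated RNA was sequenced in 12 libraries, 3 from each of 4 groups, which were control and mH2A1.2-knockdown cells at both stages. Accessible chromatin was mapped by ATAC-seq, which cuts open DNA with a transposase, in 2 MB and 2 MT libraries, for which the labels name no knockdown. Chromatin immunoprecipitation (ChIP-seq) of mH2A1.2 gave 2 libraries per stage, and that of Pbx1 gave 1 library per stage.

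The RNA values were RPKM, so the number of reads behind them is not known. Relative depth was read from the lowest values, which step by what 1 read is worth, and set against replicate 1 of the control MB group. It was 0.98 and 1.8 in the other control MB libraries, 0.55, 0.49 and 0.42 in control MT, 0.78, 0.85 and 2.03 in knockdown MB, and 0.8, 0.55 and 0.64 in knockdown MT. These readings are rough: in control MT replicate 3 the commonest step held 123 genes and the next 105. Knockdown MT replicate 1, read as deeper than replicate 2, had more genes at 0 (7826 against 7258). Between 10913 and 11273 genes reached an RPKM of 1 in a library. Control MT replicates 1 and 2 were nearly the same. At an RPKM of 50 to 100 the spread of their log2 ratios was 0.0526, against 0.274 to 0.453 in the other 11 replicate pairs. They differed by less than other replicates did in each of the 4 ranges of RPKM compared and were counted as 1 sample, their mean, so n = 2 for control MT and n = 3 elsewhere. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

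A pair of RNA libraries stood apart from their groups. Myog, the gene of the differentiation factor myogenin, was at 165.5 RPKM in control MB replicate 3 and at 17.6 and 16.1 in the other control MB libraries. The mean log2 level of the sarcomere list was 3.77 in that library, against 2.11 and 2.57. Knockdown MT replicate 1 had its highest correlation across genes with a knockdown MB library (r = 0.951) and reached 0.913 within its own group. Its sarcomere level was 3.42, against 3.71 and 4.68 in the other knockdown MT libraries.

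The target gene was compared first. H2afy transcripts stood at 64.71, 73.05 and 84.06 RPKM in the control MB libraries and at 20.16, 9.446 and 11.76 in the knockdown MB libraries. The means were 73.9 ± 9.7 and 13.8 ± 5.64 (SD, n = 3 each), and H2afy fell by 2.40 on the log2(RPKM + 1) scale (SE 0.289, adjusted p = 0.0372). In MT, control libraries held 57.25, 55.57 and 33.85 RPKM and knockdown libraries held 32.15, 25.59 and 19.49. The means were 45.1 ± 16 (SD, n = 2) and 25.7 ± 6.33 (SD, n = 3), a log2 difference of -0.77 (SE 0.323) that did not pass the test at an adjusted p of 0.123. The difference between the 2 knockdown effects was 1.63 (SE 0.433, adjusted p = 0.094). H2afy2, which encodes the related variant macroH2A2, rose in knockdown MT by 1.29 (SE 0.373, adjusted p = 0.0388), while its log2 difference in MB was 0.29 (adjusted p = 0.922). RPKM of H2afy sums all its splice forms, so the level of the mH2A1.2 form itself was not measured here. The MB call on H2afy was lost without control MB replicate 1, 2 or 3 (adjusted p 0.128, 0.212 and 0.286), without knockdown MB replicate 2 or 3 (0.0731 and 0.15), without control MT replicate 3 (0.0537) and without knockdown MT replicate 2 (0.0789). It was also lost without a filter (0.082), with only the 2 groups in the fit (0.0763) and without the 2 libraries that stood apart (0.25). With the replicate numbers as a block over the 6 MB libraries the adjusted p was 0.0984, and over all 12 libraries it was 0.016. The log2 difference of H2afy in MB stayed between -2.69 and -2.18 in every setting, so the lost calls did not come with a lost fall.

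**Figure D1:**
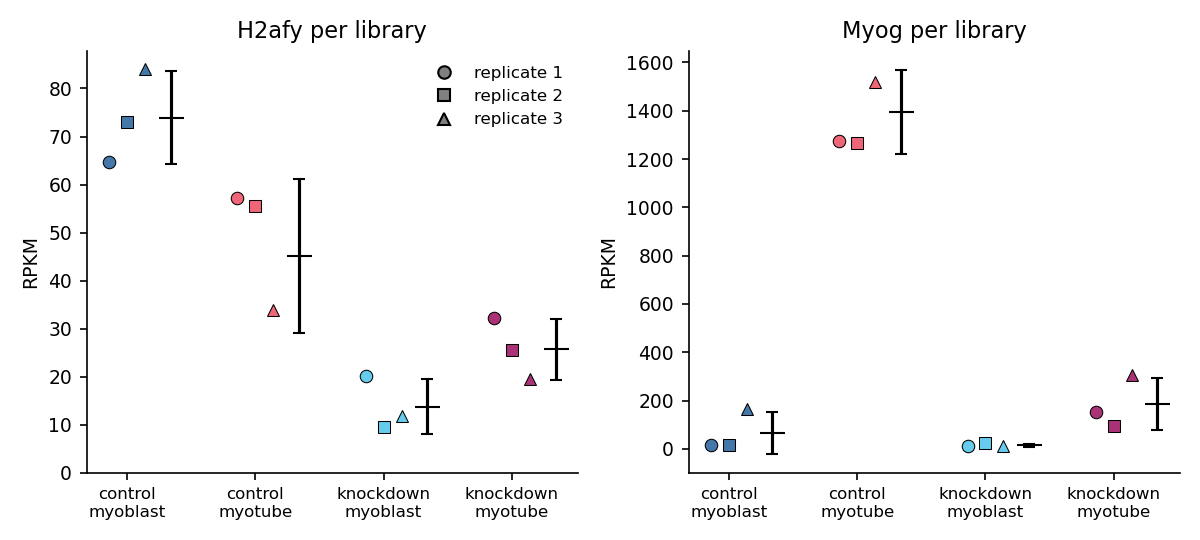
RPKM of H2afy and of Myog in each of the 12 RNA libraries, with the group on the x axis, the marker shape giving the replicate, and a black bar for the group mean ± SD (control MT over n = 2, as replicates 1 and 2 were averaged). H2afy lies between 9.446 and 20.16 in the knockdown MB libraries and between 64.71 and 84.06 in the control MB libraries, and Myog reaches 165.5 in 1 control MB library.

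The first comparison asked how transcripts changed as control cells went from MB to MT. Mb, the oxygen store myoglobin, went from 8.22 ± 10.6 RPKM (SD, n = 3) to 1247 ± 720 (SD, n = 2), a log2 rise of 7.65 (SE 0.981, adjusted p = 0.000777). Ckm, the muscle creatine kinase that buffers ATP, went from 6.14 ± 9.13 to 684 ± 285, and Actc1, the actin of cardiac and embryonic muscle, from 36.4 ± 52.2 to 2802 ± 1040. Id3, an inhibitor of the myogenic basic helix-loop-helix factors, fell from 446 ± 44.7 to 25 ± 5.21, by 4.12 (SE 0.358, adjusted p = 0.000177). At an adjusted p under 0.05, 1753 genes rose and 1698 fell of 11710 tested. Which direction held more calls depended on scaling and filter: 1446 rose and 2051 fell under quantile scaling, 1516 and 1934 under median scaling, and 2146 and 1535 without a filter.

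The sarcomere list, the contractile apparatus, held 46 tested genes, of which 43 rose and 1 fell; adjusted over the list alone, 44 rose and 1 fell. Its median log2 change was 4.68 (camera adjusted p = 6.49e-23; adjusted p = 0.431 with an estimated correlation). Embryonic myosin Myh3 rose by 7.58 (adjusted p = 0.000942), fast troponin C Tnnc2 by 7.15 (0.00193) and the thick filament protein Mybph by 7.12 (0.0014), while Tpm3, a tropomyosin with a non-muscle form, fell by 1.21 (0.00677). Of 27 genes of excitation-contraction coupling and the neuromuscular junction, 25 rose and none fell in limma, also adjusted over the list alone, with a median of 2.21 (adjusted p = 2.81e-14; 0.431 with an estimated correlation). Casq2, a calcium-binding protein of the sarcoplasmic reticulum, rose by 6.10 (adjusted p = 0.00202) and the calcium pump Atp2a1 by 5.91 (0.0017). Among 22 genes of fusion and adhesion, 10 rose and 2 fell (10 and 3 adjusted over the list alone), with a median of 0.68 (adjusted p = 0.00374; 0.526 with an estimated correlation). Itgb1bp2 (melusin), which binds integrin beta 1 in striated muscle, rose by 6.38 (adjusted p = 0.000258), and Gm7325, the fusion peptide myomixer, by 5.75 (0.000719), while the tetraspanin Cd9, a membrane protein, fell by 1.11 (0.0235).

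Cell cycle genes fell as a group. All but 1 of the 35 DNA replication genes fell, and all 35 did when adjusted over the list alone, with a median of -1.46 (camera adjusted p = 2.74e-20; adjusted p = 0.431 with an estimated correlation). Thymidine kinase Tk1 fell from 75.6 ± 9.55 to 16.5 ± 5.52 RPKM, by 2.16 (SE 0.32, adjusted p = 0.00147), and Mcm5, a subunit of the replicative helicase, by 1.90 (adjusted p = 0.000802). Of 30 mitosis genes 27 fell, also adjusted over the list alone, with a median of -1.60 (adjusted p = 5.51e-14; 0.526 with an estimated correlation). Survivin (Birc5), which acts in chromosome segregation, fell by 2.09 (adjusted p = 0.00117) and the mitotic kinase Plk1 by 1.93 (0.00177). Among 17 cell cycle inhibitors and exit genes, 6 rose and 5 fell (8 and 5 adjusted over the list alone; list adjusted p = 0.244). The CDK inhibitor Cdkn1a (p21) rose from 142 ± 54.5 to 1039 ± 56.6 RPKM, by 2.93 (SE 0.335, adjusted p = 0.000511), and cyclin D1 (Ccnd1) fell from 132 ± 36.1 to 16.2 ± 12.6, by 3.14 (SE 0.468, adjusted p = 0.00152).

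The 20 myogenic regulators went both ways, with 8 higher and 4 lower (8 and 5 adjusted over the list alone), a median of 0.43 and an adjusted p of 0.148. Myogenin rose from 66.4 ± 85.8 to 1394 ± 175 RPKM, by 5.21 (adjusted p = 0.00272), and the Z-disc protein Csrp3 by 5.44 (0.000985), while Id2 fell by 2.59 (0.00966). Myod1, the myoblast determination factor, was outside the naming rule and stood at 159 ± 20.4 and 208 ± 1.18, a log2 difference of 0.40 (adjusted p = 0.398). Inflammatory and secreted factors were lower as a list (median -1.20, adjusted p = 0.0228; 0.678 with an estimated correlation), with 2 of 20 higher and 9 lower (3 and 11 adjusted over the list alone). The growth factor Csf1 fell by 2.51 (adjusted p = 0.00398) and the chemokine Ccl2 by 2.42 (0.0334). Notch and TGF-beta family genes were higher (median 0.61, adjusted p = 0.0352; 0.576 with an estimated correlation), with 9 of 25 higher and 2 lower (15 and 2 adjusted over the list alone). Follistatin (Fst), which binds activins and myostatin, rose from 3.86 ± 1.06 to 86.6 ± 38.7 RPKM, by 4.12 (adjusted p = 0.000995), and Lfng, a modifier of Notch, fell by 2.25 (0.000578). Nuclear genes of the respiratory chain were higher (median 0.20, adjusted p = 0.0372; 0.768 with an estimated correlation), with 5 of 39 past the test, also adjusted over the list alone, among them the muscle subunits Cox6a2 (6.26, adjusted p = 0.00131) and Cox8b (5.45, 0.00891). Histone variants and chaperones were lower (median -0.41, adjusted p = 0.0333; 0.526 with an estimated correlation), with 9 of 24 lower, also adjusted over the list alone, such as Chaf1b (-1.82, 0.000278) and H2afz (-1.98, 0.0461). Ribosomal proteins, whose reads can map to many near-identical copies and are uncertain for that reason, were lower (median -0.34, adjusted p = 0.0333; 0.751 with an estimated correlation), with 2 of 44 lower (1 adjusted over the list alone).

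Other lists did not pass the test. The genes of glycolysis and creatine metabolism had a median of 0.26 (8 of 23 higher and 3 lower; adjusted p = 0.0881) and the p53 targets one of 0.25 (4 of 20 higher and 2 lower; 0.218). Splicing regulators had a median of 0.51 (7 of 16 higher and 1 lower; 0.13), insulin-like growth factor genes 0.74 (6 of 20 higher and 2 lower; 0.113) and H3K27 writers and erasers 0.25 (4 of 28 higher and 6 lower; 0.572). The unfolded protein response gave 0.04 (6 of 25 higher and 1 lower; 0.678), and the TALE and Hox genes gave -0.11 (2 of 22 lower; 0.227). For extracellular matrix genes the median was -0.06 while the mean was 0.34 and the test pointed up (7 of 32 higher and 1 lower; 0.765). For cholesterol synthesis the median and mean were -0.06 and -0.03 while the test pointed up (0.978); none of its 22 genes passed in limma. Adjusted over the list alone, the counts of these lists differed for splicing regulators, with 8 higher and 1 lower. Within these lists, the glycogen phosphorylase Pygm rose by 5.40 (adjusted p = 0.000777), Rbm24, a splicing factor of muscle, by 3.29 (0.0116), Msi2 by 2.37 (0.0023), Col1a1 by 3.20 (0.0147) and Igf2 by 3.41 (0.0177). The splicing repressor Ptbp1 fell by 1.56 (0.000726).

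Of the 83 named genes past the test in this comparison, 43 still passed without control MT replicate 3, which leaves the near-identical pair as the only control MT sample, and the counts were then 633 higher and 375 lower. Without control MB replicate 1, 2 or 3, 69, 68 and 74 of the 83 passed; without replicate 2 the count of genes lower was 1027. The list calls of the respiratory chain (adjusted p = 0.68), inflammatory factors (0.0687) and histone variants (0.0543) were lost without control MT replicate 3, that of ribosomal proteins without control MB replicate 2 (0.128) and under median scaling (0.0551), and that of Notch and TGF-beta genes without control MB replicate 1 (0.0634), without a filter (0.0557) and at a mean RPKM of at least 5 (0.0649), which also ended the ribosomal call (0.0504). The respiratory chain call was also lost without control MB replicate 1 (0.0786) or 2 (0.0652) under quantile (0.0837) or median scaling (0.0564), without a filter (0.0665), with 12 separate libraries (0.115) and with the block over them (0.0758), which also ended that of histone variants (0.0758). Of genes listed at 0 in all MB libraries, 38 had a mean of at least 10 RPKM in MT, and 28 showed the opposite. Of these 66, 62 were small RNA genes. Eef1a1, a translation factor used by every cell, was listed at 0 in the 6 MB libraries and at 929.4, 942.8 and 1240 in control MT and 1268, 873.1 and 816.1 in knockdown MT, and Filip1l at 0 in the 6 MT libraries and at 16.78 to 37.44 in MB.

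The knockdown was then compared with control in MB, before differentiation. Besides H2afy, Ppp1r14c, an inhibitor of protein phosphatase 1, fell from 15.1 ± 2.75 to 3.61 ± 1.27 RPKM (SD, n = 3 each), by 1.83 (SE 0.218, adjusted p = 0.0372). Mir700, named after its values were seen, was listed at 0 in all 3 knockdown MB libraries and at 238.1, 97.13 and 133.4 RPKM in control MB. This small RNA gene was also listed at 0 in every MT library, control included, so its 0 values can be failed estimates. Without genes listed at 0 and small RNA genes, 2 genes were called for the knockdown in MB, both lower. Muscle regulators did not pass the test: Myog was at 66.4 ± 85.8 and 14.8 ± 7.05 RPKM (log2 difference -1.34, adjusted p = 0.741), Myod1 at 159 ± 20.4 and 84.2 ± 35.9 (-0.99, 0.335), and Id3 at 446 ± 44.7 and 472 ± 48.8 (0.08, 0.987). Cell cycle genes such as Rrm2 (-0.33, adjusted p = 0.784), Mcm6 (-0.10, 0.953) and Birc5 (-0.32, 0.862) did not pass either, nor did the acetylcholine receptor subunit Chrna1 (-1.14, 0.472) or the growth factors Bmp4 (1.01, 0.5) and Tgfb3 (0.80, 0.423). With limma, 0 genes rose and 3 fell (418 and 573 at an unadjusted p under 0.05); with the replicate block 6 rose and 30 fell over all 12 libraries, and 2 rose and 1 fell over the 6 MB libraries. Counted as 12 separate libraries, the numbers were 2 and 14. Leaving out 1 library gave 0 to 1 higher and 1 to 7 lower. The Ppp1r14c call was lost without control MB replicate 1, 2 or 3, knockdown MB replicate 2 or 3, control MT replicate 3 or knockdown MT replicate 2. It was also lost without a filter, with only the 2 groups in the fit, with the block over 6 libraries and without the 2 libraries that stood apart. Over all settings its adjusted p in limma ran from 0.016, where the call was kept, to 0.286. Its log2 difference stayed between -2.08 and -1.64.

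Several lists were lower in knockdown MB although their members did not pass alone. Excitation-contraction coupling genes had a median of -0.54 (camera adjusted p = 8.36e-05; 1 higher and 2 lower adjusted over the list alone), and cholesterol synthesis genes a median of -0.37 (7.23e-05). Mitosis genes had a median of -0.20 (adjusted p = 0.005; 1 lower adjusted over the list alone), respiratory chain genes -0.14 (0.0124) and genes of the unfolded protein response -0.18 (0.0142). None of these 5 calls held with an estimated correlation (adjusted p = 0.927 for each) or in fry (0.933). The sarcomere list gave -0.24 (adjusted p = 0.0634), and DNA replication genes had a median of -0.002 and a mean of 0.03 (0.73). Control MB replicate 3, with its high muscle gene values, weighed on these tests: without it the excitation-contraction median was -0.27 (adjusted p = 0.0572), and the respiratory (0.275) and unfolded protein (0.0916) calls were lost. Without knockdown MB replicate 2 the cholesterol (median -0.09, adjusted p = 0.512), mitosis (0.0973), respiratory (0.0858) and unfolded protein (0.0542) calls were lost. The mitosis call was also lost without control MB replicate 2 (0.151) and the unfolded protein call without control MB replicate 1 (0.0514). Quantile scaling ended the respiratory (0.11) and unfolded protein (0.1) calls. Without knockdown MB replicate 3 the excitation-contraction median was -0.32 (0.00648).

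The same comparison in MT asked whether cells given the knockdown reached the control state after differentiation. Muscle genes were far lower in knockdown MT. Myoglobin fell from 1247 ± 720 RPKM (SD, n = 2) to 27.3 ± 22.9 (SD, n = 3), by 5.63 (SE 0.981, adjusted p = 0.00582), and perinatal myosin Myh8, at 102 ± 85.8 and 0.984 ± 1.17, fell by 5.55 (SE 0.606, adjusted p = 0.000891). Ckm went from 684 ± 285 to 26.3 ± 14, by a fall of 4.71 (SE 0.873, adjusted p = 0.0077). Cyclin D1 rose from 16.2 ± 12.6 to 116 ± 41.2 RPKM, by 2.93 (SE 0.468, adjusted p = 0.00406), and Cdkn1a, at 1039 ± 56.6 and 237 ± 49.2, fell by 2.15 (SE 0.335, adjusted p = 0.00368). In total 979 genes rose and 1248 fell, against 1251 and 1108 under quantile scaling, 1130 and 1111 under median scaling and 794 and 1497 without a filter.

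Of the 46 sarcomere genes, 44 fell and none rose in limma; adjusted over the list alone, 44 fell and 1 rose. The median was -3.72 (camera adjusted p = 2.64e-22; adjusted p = 0.506 with an estimated correlation), and fry gave 0.00338. Alpha-actinin Actn2, a Z-disc protein, fell by 5.01 (adjusted p = 0.00492), and the stretch-related muscle proteins Ankrd2 and Smpx by 5.32 (0.00224) and 5.04 (0.00298). All but 1 of the 27 excitation-contraction genes fell, and all 27 did when adjusted over the list alone, with a median of -2.18 (adjusted p = 2.89e-16; 0.506 with an estimated correlation). The voltage-sensing calcium channel Cacna1s fell from 70.3 ± 38.1 to 2.18 ± 1.5 RPKM, by 4.48 (SE 0.519, adjusted p = 0.00124), and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, by 4.16 (0.00298). Among fusion and adhesion genes 10 fell and 2 rose (12 and 2 adjusted over the list alone), with a median of -0.72 (adjusted p = 0.00351; 0.582 with an estimated correlation). Melusin fell by 5.07 (adjusted p = 0.00152) and caveolin 3 (Cav3) by 3.99 (0.00727), whereas Cd9 rose by 1.37 (0.0164). Tmem8c, the fusion protein myomaker, was outside the naming rule and fell by 3.83 (0.0088).

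DNA replication and mitosis genes were higher in knockdown MT. Of 35 replication genes, 32 rose (33 adjusted over the list alone) and none fell in limma, with a median of 1.06 (camera adjusted p = 1.52e-18; adjusted p = 0.506 with an estimated correlation). Tk1 rose from 16.5 ± 5.52 to 55.4 ± 23.3 RPKM, by 1.65 (adjusted p = 0.00923), and Gins2, a part of the replicative helicase, by 1.51 (0.0058). Of 30 mitosis genes, 24 rose (26 adjusted over the list alone), with a median of 1.07 (adjusted p = 2.32e-12; 0.612 with an estimated correlation), among them the kinase Aurkb (1.33, adjusted p = 0.0118) and Birc5 (1.32, 0.0159). The cell cycle inhibitor list itself was mixed, with 4 higher and 5 lower, also adjusted over the list alone (median -0.28, adjusted p = 0.291); Cdkn1c (p57) fell by 4.52 (0.0342) and Rbl1, a pocket protein related to the retinoblastoma protein, rose by 0.85 (0.033). The p53 target list had 2 genes higher and 5 lower, also adjusted over the list alone (median -0.44, adjusted p = 0.0873), where Pmaip1, a gene of the cell death machinery, fell by 2.36 (0.00409) and Eda2r fell by 2.21 (0.0048).

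Myogenic regulators gave 2 genes higher and 9 lower (3 and 9 adjusted over the list alone; median -0.35, adjusted p = 0.0873). Mef2c, a partner of the myogenic factors, fell by 3.52 (adjusted p = 0.0082) and Csrp3 by 4.37 (0.00496), while Id3 rose by 1.65 (0.0141) and Tcf3, the dimer partner of Myod1, by 0.81 (0.0276). Myod1, outside the naming rule, fell from 208 ± 1.18 to 98.7 ± 31.3 RPKM, by 1.11 (SE 0.336, adjusted p = 0.045). Pbx1, which encodes the factor mapped by ChIP, rose from 9.64 ± 2.92 to 22.9 ± 8.99 RPKM, by 1.12 (SE 0.313, adjusted p = 0.0348; 0.0064 to 0.318 over 23 alternatives), and its log2 difference in MB was 0.50 (adjusted p = 0.725). Meis3, of the same TALE family, rose by 1.04 (0.00621), and the TALE and Hox list had 2 genes higher (1 adjusted over the list alone) and a median of 0.34 (adjusted p = 0.0989). Respiratory chain genes were lower (median -0.38, adjusted p = 0.000165; 0.663 with an estimated correlation), with 6 of 39 lower (5 adjusted over the list alone), such as Cox6a2 (-4.32, adjusted p = 0.0126). Inflammatory and secreted factors were higher (median 0.73, adjusted p = 0.0327; 0.663 with an estimated correlation), with 5 of 20 higher and 1 lower (7 and 2 adjusted over the list alone), such as the chemokines Cxcl12 (1.77, adjusted p = 0.00505) and Cxcl5 (1.41, 0.0112).

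Other lists were short of the test. Notch and TGF-beta genes had a median of -0.36 (adjusted p = 0.0541), with 1 of 25 higher and 5 lower (1 and 6 adjusted over the list alone), and Fst fell by 3.74 (0.00306). Histone variants had a median of 0.18 (0.0541; 6 of 24 higher), and Chaf1b, a subunit of a histone H3 and H4 chaperone, rose by 1.41 (0.00176). Glycolysis genes gave -0.30 (0.0873; 9 of 23 lower) and the muscle enzyme Pgam2 fell by 4.23 (0.00417), and insulin-like growth factor genes gave -0.47 (0.212; 2 of 20 higher and 5 lower), where Igf2 fell by 3.61 (0.0216). The unfolded protein response gave -0.31 (0.0989; 5 of 25 lower), and Herpud1, a factor in the disposal of misfolded proteins, fell by 1.89 (0.00176). The last 4 counts were the same adjusted over the list alone. Splicing regulators gave -0.36 (0.36; 1 of 16 higher and 4 lower, 2 and 6 adjusted over the list alone), and Rbm38 fell by 1.98 (0.00386). Extracellular matrix genes gave 0.34 (0.0873; 4 of 32 higher and 1 lower) and cholesterol synthesis 0.29 (0.0873; 1 of 22 higher); neither list had a call in limma adjusted over the list alone. Ribosomal proteins gave 0.12 (0.291) and no call in limma among 44. H3K27 writers and erasers had a median of -0.01 while the test pointed up (0.743), with 2 of 28 higher and 3 lower (2 and 2 adjusted over the list alone); in that list the methyltransferase Ezh2 rose by 0.72 (0.00798) and its relative Ezh1 fell by 0.53 (0.0338).

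Without control MT replicate 3, 15 of the 77 named genes past the test still passed, and the counts were 39 higher and 272 lower. With only the control and knockdown MT samples in the fit, 23 of 77 passed and the counts were 45 and 313. Without knockdown MT replicate 1 or 2, 63 and 49 of the 77 passed, and without replicate 2 the count higher was 472. The inflammatory call was lost without control MT replicate 3 (0.124) or knockdown MT replicate 1 (0.168) under quantile scaling (0.0575), with 12 separate libraries (0.0538) and without the 2 libraries that stood apart (0.173), and the respiratory call without control MT replicate 3 (0.0645).

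**Figure D2:**
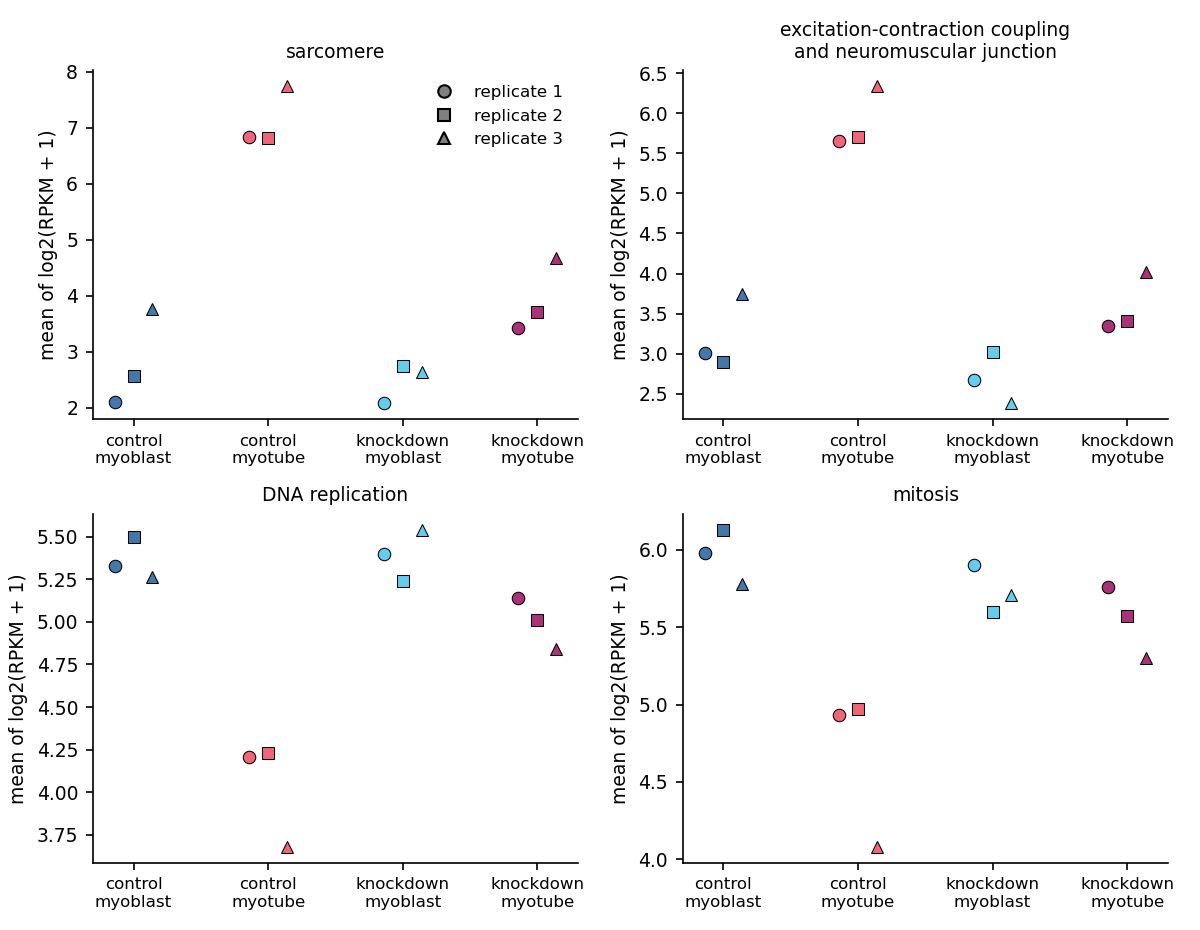
Mean log2(RPKM + 1) of the genes of 4 lists in each of the 12 RNA libraries, by group, with the marker shape giving the replicate. Sarcomere levels are 6.82 to 7.74 in control MT and 3.42 to 4.68 in knockdown MT, and DNA replication levels are 3.68 to 4.23 and 4.84 to 5.14.

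Differentiation was also tested within the knockdown cells. Id3 fell from 472 ± 48.8 to 87.7 ± 46.1 RPKM (SD, n = 3 each), by 2.55 (SE 0.32, adjusted p = 0.0237), and Rasl11a, a small GTPase of the Ras family, by 1.81 (SE 0.221, adjusted p = 0.0216). Sepw1, a selenoprotein of muscle, rose from 95.2 ± 14.7 to 227 ± 20.2 RPKM, by 1.26 (SE 0.164, adjusted p = 0.0277), and Pdk1, a kinase that limits the entry of pyruvate into mitochondria, by 1.17 (SE 0.155, adjusted p = 0.0282). The myosin light chain Mylpf, at 67.3 ± 54.2 and 244 ± 105 RPKM (2.24, adjusted p = 0.418), and Cdkn1a (1.01, 0.267) did not pass. In total 4 genes rose and 6 fell with limma (724 and 660 at an unadjusted p under 0.05). Among them Eef1a1 and Ubc, which rose, and Filip1l, which fell, were listed at 0 throughout 1 stage, and without genes listed at 0 the counts were 2 and 2. In the lists that follow, 0 members passed in limma when adjusted over all genes, and the counts given are those adjusted over the list alone. Sarcomere genes were higher (median 1.38, camera adjusted p = 2.15e-14; 19 of 46), as were excitation-contraction genes (0.74, 6.46e-09; 6), fusion genes (0.27, 0.00114; 5 higher and 1 lower), cholesterol synthesis (0.74, 1.22e-11; 12), extracellular matrix (0.35, 0.000709; 1), glycolysis (0.26, 0.00315; 1) and splicing regulators (0.33, 0.0105; 3 higher and 1 lower). DNA replication (-0.39, 3.52e-12), mitosis (-0.24, 0.0172) and ribosomal proteins (-0.27, 0.00519) were lower. None of these calls held with an estimated correlation, where the lowest adjusted p was 0.491.

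Without knockdown MT replicate 1, whose values lay nearest to MB, 194 genes rose and 73 fell in knockdown cells, and without both libraries that stood apart the counts were 262 and 67. Without control MB replicate 3, 20 rose. Of Id3, Rasl11a, Sepw1 and Pdk1, the 4 named genes that passed, 0 passed in limma without control MB replicate 2 or knockdown MT replicate 2, without a filter or with only the 2 groups in the fit. Without control MB replicate 1, knockdown MB replicate 2 or 3, or knockdown MT replicate 3, 1 passed, without knockdown MB replicate 1, 2 did, and without control MT replicate 3, 3 did. The list calls for glycolysis without knockdown MB replicate 2 (adjusted p = 0.102), knockdown MT replicate 1 (0.148) or both libraries that stood apart (0.0894), and for mitosis without knockdown MB replicate 1 (0.301) or knockdown MT replicate 3 (0.46), were lost. So were those of splicing regulators without knockdown MB replicate 1 (0.0786) or knockdown MT replicate 2 (0.0535) or 3 (0.0526), and of ribosomal proteins without knockdown MT replicate 2 (0.26) or 3 (0.0526).

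The changes of the same genes were then set side by side in both kinds of cells. Over the genes called in control differentiation, the log2 change in knockdown cells had a slope of 0.32 on that in control cells (r = 0.816 across genes, which are not independent replicates). The slope was 0.309 over genes that rose and 0.348 over those that fell, and 0.297 over all tested genes (r = 0.602). The change was smaller in knockdown cells for 99.1% of the called genes and for 76.9% of all tested genes. The control values share no library with the knockdown values, but the genes were chosen on the control change, which by itself lowers the slope. The interaction test, which asks whether the knockdown effect differed between stages, called 21 genes higher and 191 lower, such as Myh8 (-5.30, SE 0.813, adjusted p = 0.0173), Cacna1s (-4.25, 0.0213), Fst (-4.75, 0.0178) and Mcm3, a helicase subunit (1.36, 0.0337). Birc5 (1.63, adjusted p = 0.0726), Cdkn1a (-1.92, 0.0654) and Myog (-1.72, 0.481) did not pass.

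**Figure D3:**
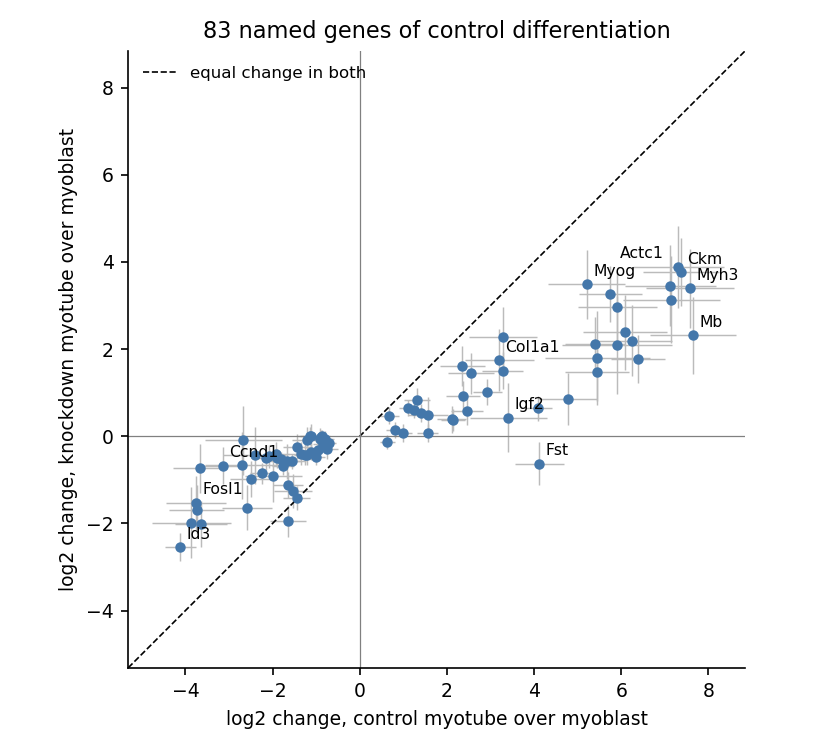
Log2 change from MB to MT of the 83 genes named for control differentiation, with control cells on the x axis and knockdown cells on the y axis, bars giving the standard error and the dashed line equal change. Most points lie nearer to 0 on the y axis than on the x axis; the slope over all genes called in control differentiation is 0.32.

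Genes that rose in control differentiation were compared with those that fell with the knockdown in MT. Calls overlapped in opposite directions: 1026 genes rose in control differentiation and fell with the knockdown in MT, where independent lists would share 186.8, and 751 fell and then rose, against 142. In the same direction 1 gene was higher in both (146.6 for independent lists) and 0 were lower in both (181) by limma. Both contrasts use the control MT libraries, with opposite signs. In 100 simulations with unchanged groups and shared controls 1.37 genes on average were called in opposite directions, but such groups hold no true change to call, so this value is no measure for the 1777 observed. The correlation of log2 changes across genes was -0.847 (simulated mean -0.581, 95% range -0.952 to -0.0156), and 82.3% of genes had opposite signs (simulated 48.9 to 90.7%), so both lay within what shared controls give. The covariance was -0.675 (simulated mean -0.117, 95% range -0.336 to -0.00108), a difference of -0.558 from that mean, and lay below that range. The control MT samples were too few to split, so how much of the opposite calls comes from the shared controls is not known. Without control MT replicate 3 the opposite calls numbered 294, and without knockdown MT replicate 2 they numbered 1132.

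ATAC peaks, which mark open chromatin, were compared between stages as counts, and no test between the 2 libraries of each stage was run. MB libraries held 72463 and 72144 peaks over 21.6 and 23.6 Mb, and MT libraries held 29846 and 29324 peaks over 6.82 and 6.71 Mb. Tags left after filtering numbered 13597165 and 18661333 in MB and 29459935 and 46717804 in MT. Peaks found in both replicates numbered 51616 in MB and 18904 in MT. Of the MB peaks, 29582 (57.3%) lay outside the peaks of both MT libraries, and of the MT peaks 2742 (14.5%) lay outside those of both MB libraries, while 15033 (79.5%) overlapped peaks shared by the MB replicates. With equal numbers of top peaks per library these counts were 9212 MB-only and 5083 MT-only, at a -log10 q of at least 10 they were 16489 and 543, and with replicate 1 or 2 left out they were 53040 to 53119 and 8745 to 9128, so the size of the difference depends on how peaks were chosen. By the score of the peak caller, the strongest MB-only regions (mm9) were on chromosome 1 from 96046311 to 96046946 (22.2-fold enrichment), on chromosome 12 from 91404531 to 91405009 (18.3-fold) and on chromosome 11 from 111549725 to 111550251 (17.1-fold). The strongest MT-only regions were on chromosome 18 from 89101571 to 89101856 (16.0-fold), on chromosome 8 from 49840813 to 49841420 (12.1-fold) and on chromosome 1 from 149241388 to 149241794 (13.9-fold). Scores and enrichments are the authors', and genes at these places were not annotated here. No control library was named for ATAC.

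The mH2A1.2 ChIP was examined in the same way. MB libraries held 99754 and 115733 peaks over 68.5 and 88.4 Mb from 40806780 and 47153167 filtered tags, and MT libraries held 53366 and 50397 peaks over 29.0 and 29.9 Mb from 16971251 and 26360849. Peaks in both replicates numbered 84817 in MB, of which 65142 (76.8%) were MB-only, and 37232 in MT, of which 19052 (51.2%) were MT-only. With equal numbers of top peaks 31109 were MB-only and 26133 MT-only, at a -log10 q of at least 10 they numbered 34392 and 12059, and MT-only peaks numbered 30748 to 33643 with replicate 1 or 2 left out. The strongest MB-only regions (mm9) were on chromosome 19 from 46720452 to 46722768 (15.7-fold) and on chromosome 15 from 58895080 to 58900646 (11.5-fold) and from 99161902 to 99165831 (8.44-fold). The strongest MT-only regions were on chromosome 5 from 52983087 to 52985121 (9.92-fold), on chromosome 14 from 20800341 to 20801505 (19.1-fold) and on chromosome 15 from 31923582 to 31924620 (20.0-fold). Per the labels the replicates used different antibodies, and the file headers name an IgG control in MB and an input control in MT, so the stage cannot be told apart from the control and the depth.

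Pbx1 peaks, from 1 library per stage and so without a replicate check, numbered 95816 over 32.2 Mb in MB and 36335 over 10.7 Mb in MT. Of the MT peaks 25660 (70.6%) overlapped an MB peak and 10675 (29.4%) did not; 70790 MB peaks (73.9%) had no MT peak. With equal numbers of top peaks 19868 were MB-only and 18933 MT-only, which equal totals make nearly alike by construction, and at a -log10 q of at least 10 they numbered 31599 and 6574. The strongest MB-only regions (mm9) were on chromosome 6 from 117455222 to 117456495 (58.5-fold), on chromosome 1 from 93589243 to 93590322 (76.9-fold) and on chromosome 14 from 23641618 to 23643065 (63.0-fold). The strongest MT-only regions were on chromosome 2 from 173515373 to 173515773 (31.6-fold), on chromosome 6 from 112300448 to 112300833 (40.1-fold) and on chromosome 4 from 147430341 to 147430701 (42.7-fold). The depth of these libraries is not known.

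**Figure D4:**
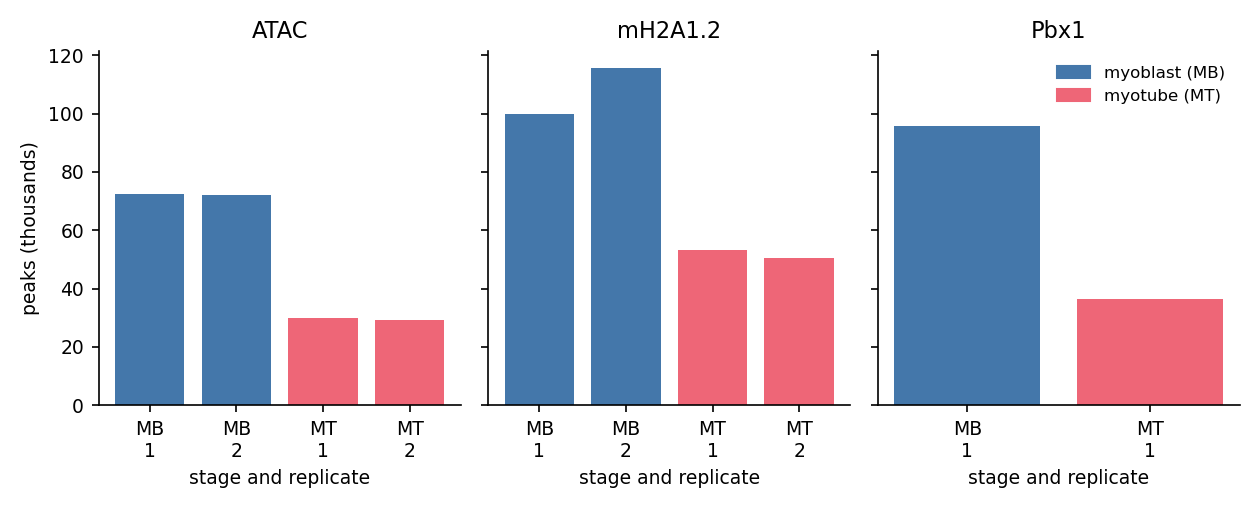
Number of peaks, in units of 1000, in each ATAC, mH2A1.2 and Pbx1 library, as bars from 0, by assay and stage. MT libraries hold 29324 to 53366 peaks and MB libraries 72144 to 115733.

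The 3 maps were then overlaid in pairs, and regions shared by all 3 were not counted. In MB, 22.8% of mH2A1.2 peaks overlapped an ATAC peak, against 2.12% after circular shifts along each chromosome (10.7 times), and in MT 5.23% against 0.617% (8.47 times). Pbx1 peaks overlapped mH2A1.2 peaks at 34.5% in MB (3.61% shifted, 9.55 times) and at 6.36% in MT (1.36% shifted, 4.67 times). They overlapped ATAC peaks at 38.5% in MB (1.38% shifted, 28.0 times) and at 33.7% in MT (0.43% shifted, 78.5 times). The MB-only ATAC peaks carried MB mH2A1.2 peaks at 36.8% (3.42% shifted) and MT mH2A1.2 peaks at 6.12% (1.29% shifted). Of the 2742 MT-only ATAC peaks, 28.6% carried an mH2A1.2 peak in MB (3.09% shifted, 9.26 times), while 40 (1.46%) carried one in MT (1.16 ± 0.223% shifted, SD over 1000 shifts; 1.26 times, permutation p = 0.21). Common ATAC peaks carried mH2A1.2 at 40.3% in MB and 15.1% in MT (3.97% and 1.57% shifted). The other 11 comparisons gave a permutation p of 0.002, the smallest that 1000 two-sided shifts can give, which is 0.0022 adjusted over the 12 comparisons. With 1 replicate per stage the MT-only ratio in MT was 3.43 to 4.58 (permutation p = 0.02). It was 2.93 at a -log10 q of at least 10 and 4.43 with equal numbers of top peaks (0.02 each). It was 1.57 at the stricter overlap (0.059), 1.24 on autosomes (0.26) and 1.01 with shifts of 1 Mb. That result thus depends on how peaks were chosen. Other ratios moved too. At a -log10 q of at least 10 that of mH2A1.2 in ATAC peaks was 13.9 in MB and 4.04 in MT, and that of common ATAC peaks in MT mH2A1.2 peaks 4.53 (9.59 with all peaks). With shifts of 1 Mb every ratio was lower, and that of Pbx1 in mH2A1.2 peaks in MT was 2.69. With equal numbers of top peaks that of MB-only ATAC in MT mH2A1.2 peaks was 2.35 (4.73 with all peaks; 3.11 at the stricter q), and those of MB Pbx1 peaks were 14.6 in mH2A1.2 and 44.5 in ATAC peaks. Peaks of any mark gather in mappable and gene-rich DNA, which circular shifts do not keep, so the ratios describe overlap beyond random placement only. The mH2A1.2 peaks were called against IgG in MB and input in MT, and depth and ATAC signal differed between stages. A stage difference in overlap therefore cannot be told apart from these.

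**Figure D5:**
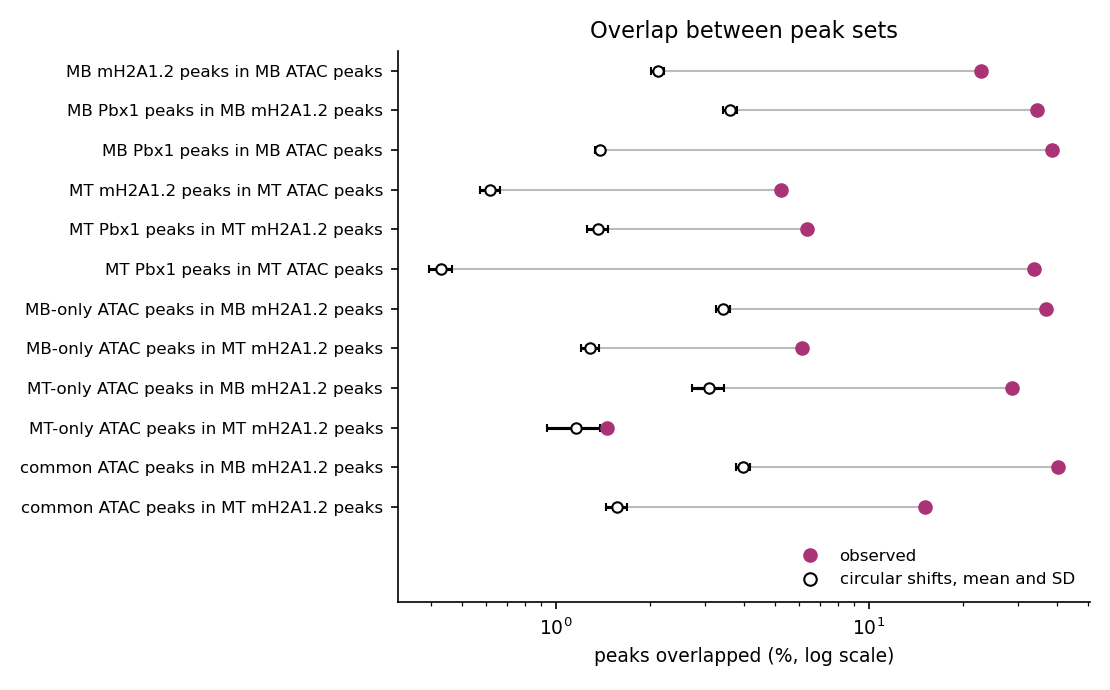
Percent of peaks overlapped by another set of peaks in 12 comparisons, on a log axis, with filled points for the observed share and open points for the mean ± SD of circular shifts. Observed shares run from 1.46% to 40.3% and lie above the mean shifted share in 12 of 12 comparisons; 11 passed the permutation test, and MT-only ATAC peaks in MT mH2A1.2 peaks (1.46%) did not.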

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

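The comparison of strength of the knockdown between stages and the counts over other splits of the samples are tests chosen only after the results were seen; the comparison of spread between stages was chosen before. The results in this part were picked out because the interaction test found that the knockdown effect in MT differed from that in MB. Values are the log2 effect in MT minus that in MB, so a negative value means a lower effect in MT.

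In limma 21 genes had a higher effect in MT and 191 a lower one (1022 and 1161 at an unadjusted p under 0.05). Without 1 library the counts were 3 and 46 (control MB replicate 1), 1 and 41 (control MB 2), 11 and 200 (control MB 3), 2 and 37 (control MT 3), 5 and 101 (knockdown MB 1), 2 and 47 (knockdown MB 2), 9 and 79 (knockdown MB 3), 8 and 86 (knockdown MT 1), 3 and 44 (knockdown MT 2) and 36 and 267 (knockdown MT 3). Lower effects were found for perinatal myosin Myh8 (-5.30, SE 0.813, adjusted p = 0.0173), the stretch-related proteins Ankrd2 (-4.93, 0.0389) and Smpx (-4.73, 0.048), melusin Itgb1bp2 (-4.61, 0.0297) and nebulin Neb (-4.41, 0.0391), the ruler of the thin filament. The calcium channel subunits Cacna1s (-4.25, adjusted p = 0.0213) and Cacnb1 (-2.78, 0.023), the membrane repair protein dysferlin Dysf (-2.80, 0.0336) and the actin-binding protein Lmod1 (-1.92, 0.0336) lay on the same side. So did follistatin Fst (-4.75, 0.0178), the NAD synthesis enzyme Itgb1bp3 (-3.46, 0.00805), muscle phosphofructokinase Pfkm (-2.42, 0.0407), brain creatine kinase Ckb (-2.15, 0.0466), the RNA-binding protein Rbm38 (-2.18, 0.0348), the retinoblastoma gene Rb1 (-1.61, 0.0348) and the interferon-induced GTPase Igtp (-1.76, 0.048), whose mean RPKM was 5.29 or less in every group. Higher effects were found for the cytoskeletal adaptor Baiap2 (1.72, adjusted p = 0.0287), the secreted protease Htra1 (1.68, 0.0167), Cdca7l (1.68, 0.0395), the peptide hormone apelin Apln (1.57, 0.0167), integrin alpha 3 Itga3 (1.53, 0.0287) and the mitotic kinase Pbk (1.46, 0.0395). The helicase subunit Mcm3 (1.36, 0.0337), the histone chaperone subunit Chaf1b (1.29, 0.0336) and the adhesion molecule Vcam1 (1.29, 0.0302) were also higher.

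By list, the sarcomere had a median of -3.33 (camera adjusted p = 7.8e-24; 13 of 46 lower, and 1 higher and 40 lower adjusted over the list alone) and excitation-contraction coupling one of -1.64 (1.28e-13; 6 of 27 lower, 20 adjusted over the list alone). DNA replication had a median of 1.03 (2.41e-21; 5 of 35 higher, 31 adjusted over the list alone) and mitosis one of 1.29 (3.22e-18; 0 of 30 in limma, and 27 higher adjusted over the list alone). Fusion and adhesion gave -0.46 (0.0257), the respiratory chain -0.26 (0.0244; -0.10 and 0.109 under quantile scaling), inflammatory factors 0.60 (0.034), TALE and Hox genes 0.30 (0.0294), histone variants 0.36 (0.00724) and cholesterol synthesis 0.70 (5.36e-05). None passed with an estimated correlation, where the lowest adjusted p was 0.434; fry gave 0.0329 for sarcomere, excitation-contraction coupling and DNA replication, and also for ADP-ribose and NAD metabolism, which camera did not call (0.244). Of these calls, the respiratory one was lost without control MT replicate 3 (0.707), knockdown MB replicate 1 (0.0539) or knockdown MT replicate 2 (0.366), and the inflammatory one without control MT replicate 3 (0.183), knockdown MB replicate 3 (0.07) or knockdown MT replicate 1 (0.225). Both were also lost under quantile scaling (0.109 and 0.0618) and with 12 separate libraries (0.0815 and 0.0606), the respiratory one without a filter (0.0518) and the inflammatory one without the 2 libraries that stood apart (0.154). The TALE and Hox call was lost without control MB replicate 3 (0.066), control MT replicate 3 (0.0504) or knockdown MT replicate 3 (0.141) and at a mean RPKM of at least 5 (0.0629), and the fusion call without knockdown MB replicate 2 (0.0522) or without a filter (0.0616).

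The calls of single genes rested on few samples, while their log2 values kept their side. Over 22 alternatives, for example, Ankrd2 lay between -5.66 and -4.28, Cacna1s between -4.69 and -3.67 and Cacnb1 between -3.01 and -2.52. Apln lay between 1.38 and 1.88 and Baiap2 between 1.34 and 1.89. Of the 25 named genes called, 25 still passed with 12 separate libraries, 18 without control MB replicate 3, 10 without the 2 libraries that stood apart, 1 without control MT replicate 3 or control MB replicate 2, 2 without knockdown MT replicate 2, 3 without control MB replicate 1 or knockdown MB replicate 2, 8 without knockdown MT replicate 1, 9 without knockdown MB replicate 1 or 3, 15 without a filter, and 0 in limma with a pseudocount of 0.1. At a mean RPKM of at least 5, 3 of the 23 that were tested passed.

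The first pattern weighed is that 2227 genes were called for the knockdown in MT (979 higher and 1248 lower; 39 and 272 without control MT replicate 3, 472 and 847 without knockdown MT replicate 2) and 3 in MB. A weaker knockdown in MB is argued against by the target gene, whose fall was larger in MB: the interaction value of H2afy was 1.63 (SE 0.433), on the side that such a cause forbids. That value did not pass the interaction test, and the fall of H2afy in MT did not pass its own test. The mH2A1.2 form itself was not measured, so its loss at either stage is not known. The spread between MB libraries was not the larger one, since the median residual SD per gene in MB was 0.792 times that in MT (0.194 and 0.245). In the fit each gene had 1 spread for all groups, so a difference in spread could not lower the calls of MB alone. What stays open, untested, is that the knockdown MT cultures had gone less far in differentiation for a reason other than the target, such as culture density, timing or another effect of the knockdown reagent. The biological hypothesis, that cells given the knockdown may differentiate less because of it, remains a hypothesis, since the pattern was found and tested on the same samples.

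Counts over other splits of the samples into groups of the same sizes bear on chance. For control differentiation the real split gave 3451 genes and the highest other 1 (1 of 10 splits as large); for the knockdown in MT 2227 and 13 (1 of 10); for differentiation in knockdown cells 10 and 6 (1 of 10); and for the knockdown in MB 3 and 5 (2 of 10). With 10 splits no share under 0.05 can be reached. Among the 4 splits of the MB libraries that part every pair of numbers, the real one gave 3 and the highest other 1; the remaining splits keep same-numbered libraries together. For the interaction, 6 of 100 splits called as many as the real 212, so chance is not excluded. The highest other called 1592, and all 5 others as large kept the MT groups as labelled, which points to a structure of the samples, the large MT difference; the highest split without those groups called 27.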

How the results depend on the processing

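The settings chosen only after the data were seen are named in the account of the processing. No list call, and no named gene past its test, changed direction; 45 of 344 values of named genes took both signs, none of them past the test under any setting (lowest adjusted p = 0.23), such as Mylpf in knockdown MB (-1.31 to 0.68). Over the alternatives, 7195 of 7889 values of named genes stayed on their side of the threshold, 680 lost a call and 14 gained one. These values include named genes that were not called with all samples. For lists 896 of 961 stayed and 65 lost a call. Only lists called with all samples were followed, so a list could not gain a call. The sarcomere, excitation-contraction, DNA replication and mitosis lists stayed called in control differentiation, in the knockdown in MT and in the interaction under every setting run, all by camera at its preset correlation. With an estimated correlation none of these lists was called in any of the 3 comparisons (lowest adjusted p 0.431, 0.506 and 0.434), and fry gave 0.0511 for mitosis in the interaction. Median shifts from another scaling stayed under 0.1 on the log2 scale. With a pseudocount of 0.1 the interaction gave 1 gene higher and 6 lower. Without a filter the knockdown in MB gave 1 gene lower, and with a mean RPKM of at least 5 it gave 7, and the interaction 3 higher and 16 lower. With only the 2 groups compared in the fit, which leaves fewer samples for the spread, the knockdown in MB gave 1 higher and 1 lower, that in MT 45 and 313, and differentiation in knockdown cells 2 and 3. The replicate block over 12 libraries gave 6 higher and 30 lower for the knockdown in MB, 1657 and 1877 for that in MT, 44 and 28 for differentiation in knockdown cells, 267 and 552 for the interaction, and 2792 genes in opposite directions in control differentiation and the MT knockdown. Pairing by number was seen in the MB libraries alone, and over those 6 the block gave 2 higher and 1 lower. It ended the calls of H2afy (adjusted p = 0.0984) and Ppp1r14c (0.108), and changed no other call on its named genes and lists. The block over 12 ended the calls of histone variants and the respiratory chain in control differentiation (0.0758 each). With 12 separate libraries the knockdown in MB gave 2 higher and 14 lower, differentiation in knockdown cells 7 higher, and the interaction 49 and 293. Without genes listed at 0, differentiation in knockdown cells gave 2 and 2. Without the 2 libraries that stood apart, the knockdown in MB gave 1 lower, that in MT 593 higher, differentiation in knockdown cells 262 and 67, the interaction 7 and 105, and opposite calls numbered 1149. With all samples, differentiation in knockdown cells and the knockdown in MB had 0 such genes in limma, which their 10 and 3 calls leave little room to differ from. Leaving out 1 library gave 633 to 2159 genes higher and 375 to 2008 lower in control differentiation, 0 to 1 and 1 to 7 for the knockdown in MB, 39 to 1008 and 272 to 1242 for that in MT, 2 to 194 and 3 to 73 for differentiation in knockdown cells, 1 to 36 and 37 to 267 for the interaction, 294 to 1794 opposite calls and slopes of 0.236 to 0.407. The lowest counts of control differentiation and of the MT knockdown were those without control MT replicate 3, where the near-identical pair stands alone as 1 sample and is taken to vary like the other groups. The highest counts of differentiation in knockdown cells were those without knockdown MT replicate 1, and 20 genes rose there without control MB replicate 3. Genes lower in knockdown MB numbered 7 without knockdown MT replicate 1 or 3, 5 without knockdown MB replicate 1, and 1 without any control MB library, control MT replicate 3, knockdown MB replicate 2 or 3, or knockdown MT replicate 2. Without control MB replicate 2, 1027 genes fell in control differentiation, and without knockdown MT replicate 2 opposite calls numbered 1132. For peaks, a -log10 q of at least 10 left 23326 ATAC peaks in MB (16489 MB-only) and 4680 in MT (543 MT-only), 41110 mH2A1.2 peaks in MB (34392) and 18161 in MT (12059), and 44340 Pbx1 peaks in MB (31599) and 19485 in MT (6574). MT-only ATAC peaks then overlapped MT mH2A1.2 peaks at a ratio of 2.93 (1.26 for all peaks). Equal numbers of top peaks gave 24126 ATAC peaks in MB, 9212 MB-only and 5083 MT-only; 39803 mH2A1.2 peaks in MB and 31109 MB-only; and 36335 Pbx1 peaks in MB, 19868 MB-only and 18933 MT-only; the ratio for MT-only ATAC peaks was 4.43. Both ratios had a permutation p of 0.02, the smallest that 100 shifts give. With shifts of 1 Mb every ratio fell (Pbx1 in mH2A1.2 peaks in MT 2.69). Leaving out a replicate gave 53040 to 53119 MB-only, 29324 to 29846 MT and 8745 to 9128 MT-only ATAC peaks, and 30748 to 33643 MT-only mH2A1.2 peaks. In these counts a single library has to hold a peak in place of both. The ratio for MT-only ATAC peaks was then 3.43 to 4.58. Why it rose, and apart from these constructions why peak numbers changed, was not tested. Summing several entries per symbol was not run, as each symbol was listed once. RNA depth is not known in reads. By the rough reading of relative depth, control MT libraries were among the shallowest (0.42 to 0.55 of control MB replicate 1), with knockdown MT replicate 2 also at 0.55. Low genes in these libraries are the least certain. The depth of the Pbx1 libraries, and how far it limits their peak numbers, is not known.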

Other observations

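The swap of labels and the comparison of tag numbers are tests chosen only after the result was seen; leaving out control MB replicate 3 and the signal at common ATAC peaks were chosen before. Markers of other cell types went both ways. Among 9 adipocyte markers, 1 rose and 1 fell in control differentiation (median -0.12, adjusted p = 0.857; the same adjusted over the list alone). The fat regulator Pparg fell by 1.65 (adjusted p = 0.00652), and Cd36, a fatty acid carrier that muscle also uses, rose by 1.58 (0.0284), to 2.4 ± 1.28 RPKM. In knockdown MT none of the 9 passed in limma (median 0.27, adjusted p = 0.842); Fasn was at 0.27 (0.54) and Cebpb at -0.31 (0.496). Of 5 bone and cartilage markers, Bmp4 fell by 1.68 in control differentiation (adjusted p = 0.0194) and rose by 2.10 in knockdown MT (0.0131; list medians -0.85 and 0.55, adjusted p = 0.616 and 0.337). Of 5 neural markers, nestin (Nes), a filament protein also of young muscle, rose by 1.24 (0.0027) in control differentiation, and its difference in knockdown MT was -1.02. Nefm fell by 2.67 (0.047) in control differentiation, and Stmn2 rose by 1.90 in knockdown MT (0.0484; list medians -1.55 and 1.73, adjusted p = 0.41 and 0.478). Too few blood and endothelial markers were expressed for a list test; Cd14 fell by 1.35 in control differentiation (adjusted p = 0.00889), from 4.88 ± 1.82 to 1.24 ± 0.358 RPKM, and rose by 1.24 in knockdown MT (0.0202), while Cd68 stood at 2.66 ± 0.122 in control MB and 1.46 ± 0.323 in control MT.

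Smooth muscle and stress fibre genes gave 4 of 19 higher and 6 lower in control differentiation (7 and 7 adjusted over the list alone; median -0.77, adjusted p = 0.857). In knockdown MT 1 rose and 5 fell (2 and 5 adjusted over the list alone), with a median of 0.18, a mean of -0.12 and a test that pointed down (0.743). Synpo2, an actin-bundling protein, rose by 2.11 in control differentiation (adjusted p = 0.00225) and fell by 2.41 in knockdown MT (0.00254), and smooth muscle actin Acta2 fell by 1.45 there (0.0217). Imprinted genes gave 4 of 14 higher in control differentiation (median 0.87, adjusted p = 0.13) and 1 higher and 4 lower in knockdown MT (median -0.50, adjusted p = 0.291), both also adjusted over the list alone; Igf2 went from 124 ± 91.5 RPKM (SD, n = 2) in control MT to 9.36 ± 7.66 (SD, n = 3) in knockdown MT. Genes of ADP-ribose and NAD metabolism gave 5 of 17 higher in control differentiation (median 0.21, adjusted p = 0.162) and 3 lower in knockdown MT (median -0.08, adjusted p = 0.185), both also adjusted over the list alone. In fry, which does not compare the list with other genes, it passed in both (adjusted p = 0.000737 and 0.00338). Itgb1bp3 (Nmrk2), a kinase of nicotinamide riboside in muscle, rose by 4.10 in control differentiation (SE 0.319, adjusted p = 9.05e-05) and fell by 3.70 in knockdown MT (adjusted p = 0.000439), and Parp3 rose by 1.12 (0.00449) and fell by 1.29 (0.00446). Interferon response genes gave 2 of 14 higher in control differentiation, with a median of -0.19, a mean of 0.06 and a test that pointed down (0.857), and 2 higher and 2 lower in knockdown MT (median 0.22, adjusted p = 0.478), both also adjusted over the list alone.

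The second pattern weighed is the lower excitation-contraction list in knockdown MB (median -0.54, adjusted p = 8.36e-05; 0.927 with an estimated correlation). It may come from 1 control library with high muscle gene values: without control MB replicate 3 the median was -0.267, 49.7% of the full value, and the call was lost at an adjusted p of 0.0572 (range over all settings 4.7e-07 to 0.0744), both close to the limits set for this test. A swap of that library with knockdown MT replicate 1 is argued against, since H2afy stood at 84.06 RPKM in control MB replicate 3, above the highest knockdown library at 32.15. A control culture that had begun to differentiate, with Myog at 165.5 RPKM, and a true fall in the other libraries, whose median was still below 0, both stay open, and neither was tested apart. The value also moved without knockdown MB replicate 3, to -0.315 (adjusted p = 0.00648), so it rests on more than 1 library, and the mean level of the list was 3.01, 2.89 and 3.74 in control MB and 2.67, 3.02 and 2.38 in knockdown MB.

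The third pattern weighed is the lower number of ATAC peaks in MT. Fewer tags are argued against, since the shallower MT library held 1.58 times the filtered tags of the deeper MB library. A lower signal over background throughout the MT libraries may account for part of it: at the 14490 peaks found in all 4 libraries the median pileup per 1e6 tags was 0.645 and 0.471 in MT and 2.13 and 1.77 in MB, a ratio of 0.286. That ratio is of the kind a library with more tags outside open regions would give, and a true loss of accessibility at the same regions stays open. A biological closing of chromatin in MT was not tested apart from library quality, because stage and library preparation go together here.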
